A study of Mus musculus with 4 samples.

How the data were processed

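Two-colour expression profiles of primary mouse aortic smooth muscle cells of the genotypes Atg7F/F and Atg7+/+, both with SM22α-Cre, were analysed from scanner files of 4 Agilent arrays. Per the labels' protocols, total RNA treated with DNase I was checked for integrity, amplified and labelled with Cy3 or Cy5. The dyes of each channel, and so the direction of each ratio, came from the labels. The labels name 2 biological replicates per genotype. The 2 arrays with the same pair of extracts were a technical dye swap and counted as 1 replicate, which gave n = 2.

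The deposited scanner files hold spot brightness as mean intensity and median local background intensity in each channel, not normalized, per the file headers. They were made by the authors with Agilent Feature Extraction 10.1.1.1, per the file headers and the submitters' processing notes. The same deposited files hold the software's background-subtracted and dye-normalized signals and a log10 ratio of Cy5 over Cy3, per the file headers. The deposited value table of the series holds log2 ratios of those processed signals by the authors, turned to Atg7F/F over Atg7+/+ on every array. For 100% of probes on every array they equalled the ratio of processed signals within 0.001, so scale, direction and the absence of further centring were settled by the values. The column medians were 0.199 and -0.094 in replicate 1 and 0.081 and -0.037 in replicate 2. Probe coordinates are those of the files, on mm9. No annotation of that build was used here, so exons and untranslated regions of probes are not stated.

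Mean intensities were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, which pulls ratios of dim spots towards 0. Each array was normalized by loess with control spots at weight 0. Ratios were turned to Atg7F/F over Atg7+/+ and the 2 arrays of a dye swap were averaged, which cancels a dye effect. Of 41174 probes on 43379 spots, 245 probes had 10 spots each, which were averaged. A probe was kept if it had no non-uniformity outlier, which 36 probes had, and was well above background in the channel of at least 1 genotype on all 4 arrays. This left 17109 probes. Of all probes, 25097 were named through RefSeq accessions and the others kept the name in the files. The brightest probe stood for each gene, which left 12367 genes. Of 3806 genes with several probes past the filter, 13 had probes that differed by at least 1 log2 unit, 9 of them also in sign.

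The 2 ratios per gene were tested against 0 with limma's lmFit and eBayes and adjusted by Benjamini-Hochberg, with an adjusted p below 0.05 as the threshold. The test is two-sided and had 3.18 degrees of freedom, 2.18 of them from the prior. Where this text gives an adjusted p, it is limma's. Of 30 gene lists, 29 had at least 2 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. That minimum was set with the measured members in view. For the 2 fits on 4 arrays the list test was cameraPR. The replicate block was part of the main test by construction, since each array holds the extracts of one number. The pairing comes from that hybridisation scheme. Deviations of same-numbered extracts from their genotype means correlated at 0.18 across genes.

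The tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule named Atg7 and, per direction, the 10 genes with the highest or lowest mean ratio among those past the test, filled with the genes of smallest unadjusted p among those at least 2-fold apart on average with one sign on all 4 arrays. It also named up to 4 members of each list with the smallest p, and Sqstm1, Nqo1, Cdkn1a, Cdkn2a, Mmp9, Cxcl12, Tgfb1, Acta2, Myh11, Tagln and Mki67. Not every gene that the rule named is reported here. Alternatives covered the normexp offset, no background subtraction, the software's processed signals, the deposited log2 table, median centring, the filter on dim probes, every probe, a trended prior variance, the 4 arrays with the pair as a random block or as independent, fits with and without the replicate block, each replicate left out, and other list tests. Quantile normalization of mean intensities between arrays leaves ratios as they are, so that alternative could move nothing, and all 4 arrays lay on 1 slide, so no slide block could be fitted.

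The code was tested on simulated data for this comparison, with 200 changed genes among the 12367. With little spread between replicates, 100% of genes changed by 1, 2, 3 or 4 log2 units were recovered. With the spread estimated from these arrays, 0% of genes changed by 1 log2 unit, 48% of those changed by 2, 80% by 3 and 90% by 4 were recovered, and 4 of 12167 unchanged genes were called. Neighbouring genes were counted within 2 Mb against 100000 random draws of tested genes. Figures were drawn with matplotlib 3.10.9.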

Results

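Primary smooth muscle cells from the mouse aorta were compared between animals homozygous for a floxed Atg7 allele (Atg7F/F) and animals with the normal allele (Atg7+/+). Both genotypes carried Cre recombinase under the SM22α promoter, which is active in smooth muscle. Atg7 is the E1-like enzyme that activates the ubiquitin-like proteins of autophagosome formation, and cells that lack it form few autophagosomes. The cells were grown in DMEM/F-12 with 10% fetal bovine serum and used at passages 4 to 10. The question was which transcripts differ between the genotypes. Each genotype had 2 biological replicates. The RNA of each Atg7F/F replicate was hybridised together with the Atg7+/+ replicate of the same number on 2 Agilent arrays with exchanged dyes, which made 4 arrays. In every channel of every array, between 43.3% and 45.5% of spots were well above background, and 0 spots were saturated. Log2 ratios are given as Atg7F/F over Atg7+/+, as the mean of the 2 replicates ± SD with n = 2, each replicate being the mean of its dye-swapped arrays. The number of replicates limits the precision of every value.

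Atg7 itself was lower in the Atg7F/F cells on each of the 4 arrays, with log2 ratios of -1.26 and -1.09 in replicate 1 and of -0.96 and -1.57 in replicate 2. The mean was -1.22 ± 0.07, which is 2.33-fold lower. The probe lies on chromosome 6 at 114726985 to 114727044 of the mm9 build and was well above background in both genotypes on all 4 arrays. Its mean log2 signals were 7.06 and 6.94 in the Atg7F/F extracts of replicates 1 and 2 and 8.23 and 8.20 in the Atg7+/+ extracts. The unadjusted p from limma was 6.07e-04 and the adjusted p was 0.938. The labels do not say which exon was floxed, so whether this probe lies in the deleted part is not known, and the other Atg7 probe was not well above background on any array. The size of the ratio depended on the processing, with -1.73 when no offset was added. It was -2.35 with the scanner software's own processed signals, in which both the background and the dye steps are the software's.

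Several detoxification genes were higher in Atg7F/F cells in both replicates. The glutathione S-transferases Gsta3 (3.27 ± 0.49, 9.62-fold), Gsta1 (3.14 ± 0.07, 8.80-fold) and Gsta4 (1.32 ± 0.18) conjugate glutathione to electrophiles, and Nqo1 (1.46 ± 0.13) reduces quinones. Mmp14, a membrane-bound matrix metalloproteinase, had a mean of 3.18 ± 0.66, and Cd200, an immunoregulatory surface glycoprotein, one of 2.20 ± 1.01. Timmdc1, an assembly factor of mitochondrial complex I, had a mean of 2.13 ± 0.25, and Gsdme, a pore-forming gasdermin, one of 1.50 ± 0.14. The growth factor Fgf7 (1.04 ± 0.11) and Rgs4, a regulator of G protein signalling (1.04 ± 0.05), completed the 10 genes of this direction. None of these 10 passed the adjusted test, in which the smallest adjusted p was 0.387 for Gsta1. The Gsta genes are close paralogs on which probes can cross-hybridise, so the values of single members are uncertain. The 2 probes of Gsta3 gave 3.27 and 2.20 and those of Rgs4 1.04 and 0.41. The 2 probes of Mmp14 disagreed, with 3.18 for the brighter one and -0.37 for the other, so its value rests on 1 probe. Their mean log2 signals were nearly equal, at 9.81 and 9.72. The first had 11.40 in Atg7F/F and 8.22 in Atg7+/+ cells, so its place as the brighter one does not make it the more reliable.

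The 10 genes named in the other direction were Atg7 and 9 more, with Gas5, Arhgap31 and Plac8 at the lowest ratios among them. Arhgap31, a GTPase-activating protein for Cdc42 and Rac1, had a mean of -2.19 ± 0.16 and Plac8 one of -1.57 ± 0.04. Ints13, a subunit of the Integrator complex, had a mean of -1.36 ± 0.25, and Erdr1 one of -1.33 ± 0.15, with -0.58 by its other probe. Fbln2, the matrix protein fibulin-2, had a mean of -1.08 ± 0.18, Plac9a of -1.18 ± 1.00, Tspan8, a tetraspanin, of -1.07 ± 0.71 and Tmem254a of -1.03 ± 0.73. Gas5, a non-coding RNA that hosts small nucleolar RNAs, had a mean of -3.44 ± 3.56, with -0.92 in replicate 1 and -5.96 in replicate 2, and its dimmer probe gave -0.26. None of these genes passed the adjusted test either.

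**Figure D1:**
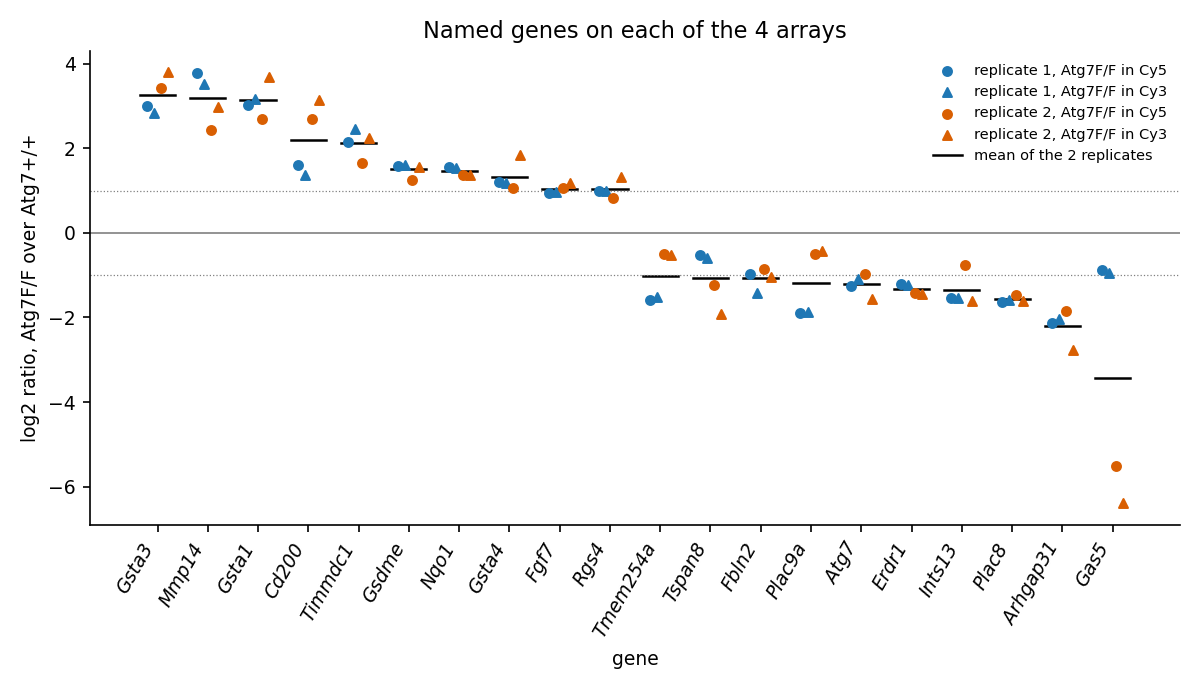
Log2 ratios (vertical axis, Atg7F/F over Atg7+/+) of the 10 named genes of each direction (horizontal axis) on each of the 4 arrays, with replicates by colour, dye orientation by marker, the mean of the 2 replicates as a black line and dotted lines at 2-fold. The 4 values of Nqo1 lie between 1.36 and 1.57, while those of Gas5 spread from -0.88 to -6.40.

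Of the 12367 genes tested, limma called 0 genes higher and 0 genes lower in Atg7F/F at an adjusted p below 0.05. At an unadjusted p below 0.05 there were 369 genes, 166 higher and 203 lower, against 618.35 that chance alone gives. With the pair of dye-swapped arrays as a random block, limma called 9 genes: Gsta1, Gsta3, Nqo1, Mmp14, Gsdme, Fgf7 and Ppfibp1 as higher, and Plac8 and Erdr1 as lower. That fit also counts agreement between technical repeats. Without the replicate block, with the extracts unpaired, it called Gsta1 alone, with an adjusted p of 0.0302. Of the genes named here, Ppfibp1 was chosen after its values were seen. An exact sign-flip test of 2 replicates cannot give a two-sided p below 0.5. By size alone, 8 genes were at least 2-fold higher on all 4 arrays (Gsta3, Mmp14, Gsta1, Cd200, Timmdc1, Gsdme, Nqo1 and Gsta4) and 3 were at least 2-fold lower (Erdr1, Plac8 and Arhgap31). Mmp14 was counted by 1 of its 2 disagreeing probes, here and in the fit with the random block. If the replicates were independent, 0.357 and 0.151 genes would reach these sizes in both. Genes 2-fold apart in opposite directions in the 2 replicates were also in excess, with 10 against 0.466. The excess of genes in one direction therefore does not by itself show agreement between the replicates. The scanner software's own processed signals gave 23 higher and 20 lower.

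Among 29 gene lists tested, 5 were called by camera with its preset correlation, and none kept an adjusted p below 0.05 with an estimated correlation or with fry. With 2 replicates these other tests have little power, so the missing calls decide little. Their smallest adjusted p over all lists was 0.886 with an estimated correlation and 0.570 with fry. Camera at the preset correlation sets the members of a list against the other genes and takes genes, not replicates, as the units. Its adjusted p-values, here and below, therefore do not measure the spread between the 2 replicates. NRF2 targets, genes of the antioxidant response, rose as a list in Atg7F/F cells. The mean log2 ratio of the 43 measured members was 0.49, with 0.50 in replicate 1 and 0.47 in replicate 2, and the adjusted p was 1.07e-14. With an estimated correlation, which was -0.019 for this list, the adjusted p was 0.886. Fry gave an unadjusted p of 0.0377 and an adjusted p of 0.570. Higher on all 4 arrays were 18 members and lower on all 4 were 0. Of all genes tested, 10.6% were higher and 9.95% lower on all 4 arrays, which is the share to set such counts against. Adjusted over the list alone, 8 members passed, against 0 over all genes tested: Gsta1, Gsta3, Nqo1 and Gsta4, and also Gstm1, Gstm3, Abcc4 and Cbr3, which were chosen for naming after their values were seen. The list was compiled with knowledge of published work on autophagy-deficient smooth muscle, so it is not fully independent evidence of its direction. Without the 10 glutathione S-transferase members, the mean of the other 33 was 0.32. Endothelial markers were lower in the same extracts, with a mean of -0.31 and an adjusted p of 5.65e-07.

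Lysosome genes, which encode acid hydrolases, membrane proteins and the proton pump of lysosomes, fell as a list. The 44 measured members had a mean of -0.19, with -0.28 in replicate 1 and -0.11 in replicate 2, and an adjusted p of 2.82e-13 (adjusted p = 0.886 with an estimated correlation). Lower on all 4 arrays were 19 members and higher on all 4 were 0, and adjusted over the list alone 0 passed. Among the members with the smallest p were the protease Tpp1 (-0.43 ± 0.01, and -0.09 by its other probe), the carboxypeptidase Ctsa (-0.40 ± 0.10) and the saposin precursor Psap (-0.37 ± 0.01). Single arrays of Psap ran from -0.63 to -0.11, a spread between dyes that the SD of dye-averaged replicates leaves out. Choosing members by small p also favours small SDs. Genes of ATG8 conjugation and autophagosome formation had a mean of -0.04 and were not called, with an adjusted p of 0.266. Ulk1, the autophagy-initiating kinase, had 0.32 ± 0.18, Gabarap -0.28 ± 0.09, Uvrag -0.24 ± 0.06 and Map1lc3b -0.15 ± 0.11, and the other probes of Ulk1 and Map1lc3b gave 0.12 and -0.05. Gabarap did not keep one sign on the 4 arrays, with values from -0.64 to 0.07. Autophagy receptors had a mean of 0.02, a median of -0.02 and an adjusted p of 0.924. Among them, Sqstm1, which encodes the receptor p62, had 0.35 ± 0.23, Bnip3l 0.32 ± 0.27, with 0.14 by its other probe, and Retreg1 -0.19 ± 0.01, none past the test. Tollip had -0.13 ± 0.01, and its other probes lay between 0.01 and 0.04. Endothelial markers were also lower in the same extracts, with a mean of -0.31.

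Endothelial markers, listed to look for other cell types in the cultures, fell as a list in Atg7F/F cells. Whether endothelial cells were present was not tested. The mean of the 16 members was -0.31, with -0.19 in replicate 1 and -0.43 in replicate 2, and the adjusted p was 5.65e-07 (adjusted p = 0.886 with an estimated correlation). Lower on all 4 arrays were 12 members and higher on all 4 were 0, and adjusted over the list alone 0 passed. The adhesion molecule Pecam1 had -0.48 ± 0.10, von Willebrand factor, Vwf, -0.70 ± 0.42, Mmrn2 -0.61 ± 0.36 and VE-cadherin, Cdh5, -0.37 ± 0.15. Markers of macrophages and leukocytes had a mean of -0.02, a median of 0.04 and an adjusted p of 0.794, -0.08 in replicate 1 and 0.04 in replicate 2, with Cd68 at -0.37 ± 0.09. Markers of adventitial fibroblasts and progenitors had a mean of 0.04 (adjusted p 0.749), with Cd34 at -0.69 ± 0.46, and osteochondrogenic markers one of 0.15 (adjusted p 0.794), with Acan, the cartilage proteoglycan aggrecan, at 0.62 ± 0.58. Adipocyte markers had a mean of 0.18 over 3 measured members (adjusted p 0.121), with Pparg at 0.32 ± 0.00. The replicate means of these lists had opposite signs, with -0.25 and 0.32 for fibroblast, -0.32 and 0.61 for osteochondrogenic and -0.07 and 0.43 for adipocyte markers in replicates 1 and 2. Neural and Schwann cell markers had a mean of 0.36 (adjusted p 0.130), 0.60 in replicate 1 and 0.12 in replicate 2, with Tubb3 at 1.04 ± 1.19. Epithelial and mesothelial markers had a mean of -0.14 over 4 members (adjusted p 0.266), 0.04 in replicate 1 and -0.33 in replicate 2, with Krt18 at -0.36 ± 0.28. Of the sex-linked transcripts 0 members passed the filter. It asks for signal on all 4 arrays, so transcripts well above background in 1 replicate alone could not pass.

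Genes of the ATF4 amino acid response, among them amino acid transporters and synthesis enzymes, rose as a list. The 33 measured members had a mean of 0.20 and an adjusted p of 5.67e-07 (adjusted p = 0.886 with an estimated correlation). Replicate 1 alone gave 0.07 and replicate 2 alone 0.33, so most of the shift came from replicate 2. Higher on all 4 arrays were 9 members and lower on all 4 were 2, where 10.6% and 9.95% of all genes tested were. Adjusted over the list alone 0 passed. Trib3, a pseudokinase, had 0.75 ± 0.18, and its other probe gave 0.46 without one sign on all 4 arrays. The glycine transporter Slc6a9 had 0.76 ± 0.64 and the cystine transporter Slc7a11, also among the NRF2 targets, 0.29 ± 0.09, while the stress-induced factor Ddit3 had -0.25 ± 0.00. The unfolded protein response had a mean of 0.04 (adjusted p 0.448), with Xbp1 at 0.32 ± 0.18 and Atf6 at -0.34 ± 0.14, whose other probe gave 0.07. The heat shock response had a mean of -0.02 (adjusted p 0.794), with Hspb1 at -0.43 ± 0.16, and proteasome subunits one of -0.01 (adjusted p 0.921), with Psmb6 at 0.16 ± 0.02. Endothelial markers, at -0.31, moved the other way in these extracts.

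The extracellular matrix list was called higher, with a mean of 0.15 over 65 members and an adjusted p of 2.51e-03 (adjusted p = 0.933 with an estimated correlation). The call rested on replicate 2, whose mean was 0.35, while replicate 1 gave -0.05. Markers of adventitial fibroblasts, at -0.25 and 0.32 in replicates 1 and 2, and osteochondrogenic markers, at -0.32 and 0.61, differed between the replicates in the same direction, and endothelial markers were lower in both, at -0.19 and -0.43. Higher on all 4 arrays were 12 members and lower on all 4 were 5, where 10.6% and 9.95% of all genes tested were. Adjusted over the list alone 0 passed. The collagens Col5a3 (1.04 ± 0.53) and Col15a1 (0.94 ± 0.41) and the microfibril protein Mfap2 (0.59 ± 0.33) were higher on average, and Fbln2 was lower, at -1.08. Matrix proteases had a mean of 0.24, a median of 0.12 and an adjusted p of 0.135 over 21 members. Adjusted over the list alone 1 member passed, Mmp14, whose probes disagreed and whose 3.18 raised this mean. The gelatinase Mmp2 had -0.32 ± 0.11, without one sign on all 4 arrays, and Adamts9 0.34 ± 0.05. Secretory factors associated with senescence had a mean of 0.10, a median of -0.03 and an adjusted p of 0.742, and adjusted over the list alone 2 members passed, Mmp14 and Fgf7. In that list the plasminogen activator Plat had 0.52 ± 0.03, with 0.15 by its other probe, and the chemokine Ccl5 0.67 ± 0.41, while Mmp9 was not measured above the filter. The response to TGF-beta had a mean of -0.04, a median of 0.01 and an adjusted p of 0.742, with Tgfb3 at -0.40 ± 0.24 and Tgfb1 at -0.09 ± 0.27.

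Contractile genes of smooth muscle had a mean of -0.04 over 38 members and an adjusted p of 0.0808, so they were not called. The smooth muscle actin Acta2 had -0.17 ± 0.01, Tagln, which encodes SM22α, -0.23 ± 0.06 and the heavy chain Myh11 -0.14 ± 0.56, and tropomyosin 1, Tpm1, had -0.39 ± 0.20. Aebp1, named by its small p with a mean of -0.56 ± 0.36, had opposite signs on the dye-swapped arrays, at 1.03 and -2.66 in replicate 1 and 1.21 and -1.81 in replicate 2, the sign following the dye. Proliferation genes had a mean of 0.06 (adjusted p 0.0808), with 0.18 in replicate 1 and -0.06 in replicate 2. Prc1 had 0.47 ± 0.12, Kif20a 0.38 ± 0.20 and Mki67, a marker of cycling cells, -0.03 ± 0.30. Cell cycle inhibitors with lamin B1 had a mean of 0.06 (adjusted p 0.266), with Cdkn1b (p27) at 0.40 ± 0.03 by the brighter probe and -0.06 by the other, Cdkn1a (p21) at -0.03 ± 0.16 and Cdkn2a (p16 and p19) at 0.00 ± 0.07. Targets of p53 had a mean of -0.01, a median of 0.02 and an adjusted p of 0.742, with Perp at -0.69 ± 0.13 and Fas at -0.33 ± 0.13.

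Interferon-stimulated genes had a mean of 0.04 (adjusted p 0.742), with -0.20 in replicate 1 and 0.27 in replicate 2, and Bst2 was at -0.59 ± 0.22. Chemokines and leukocyte adhesion genes had a mean of -0.05 (adjusted p 0.420), with Cx3cl1 at 0.41 ± 0.23 and Cxcl12, a chemokine for progenitor cells, at -0.01 ± 0.22. Genes of cholesterol synthesis had a mean of 0.03 (adjusted p 0.794), with the squalene epoxidase Sqle at 0.31 ± 0.35. Genes of cholesterol efflux and lipid storage had a mean of -0.04 and a median of 0.01 (adjusted p 0.749), with the desaturase Scd2 at 0.60 ± 0.18 and Lpl at 0.34 ± 0.21. Genes of hypoxia and glycolysis had a mean of 0.06 (adjusted p 0.266), with the oxidoreductase Ero1a at 0.66 ± 0.21 and its other probe at 0.28, and genes of oxidative phosphorylation one of -0.04 (adjusted p 0.135), with Cox7a2 at -0.28 ± 0.18. For 7 of the 24 lists not called, the mean, the median and the direction of the test differed in sign: autophagy receptors, p53 targets, secretory factors, the TGF-beta response, proteasome subunits, cholesterol efflux with lipid storage, and macrophage markers. The means of the 24 lists lay between -0.14 and 0.36, and 10 of the 29 lists changed sign when arrays were median-centred in place of loess, none of them called. Without replicate 1 the mean of 3 lists changed sign and without replicate 2 that of 12, the extracellular matrix list among the latter.

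**Figure D2:**
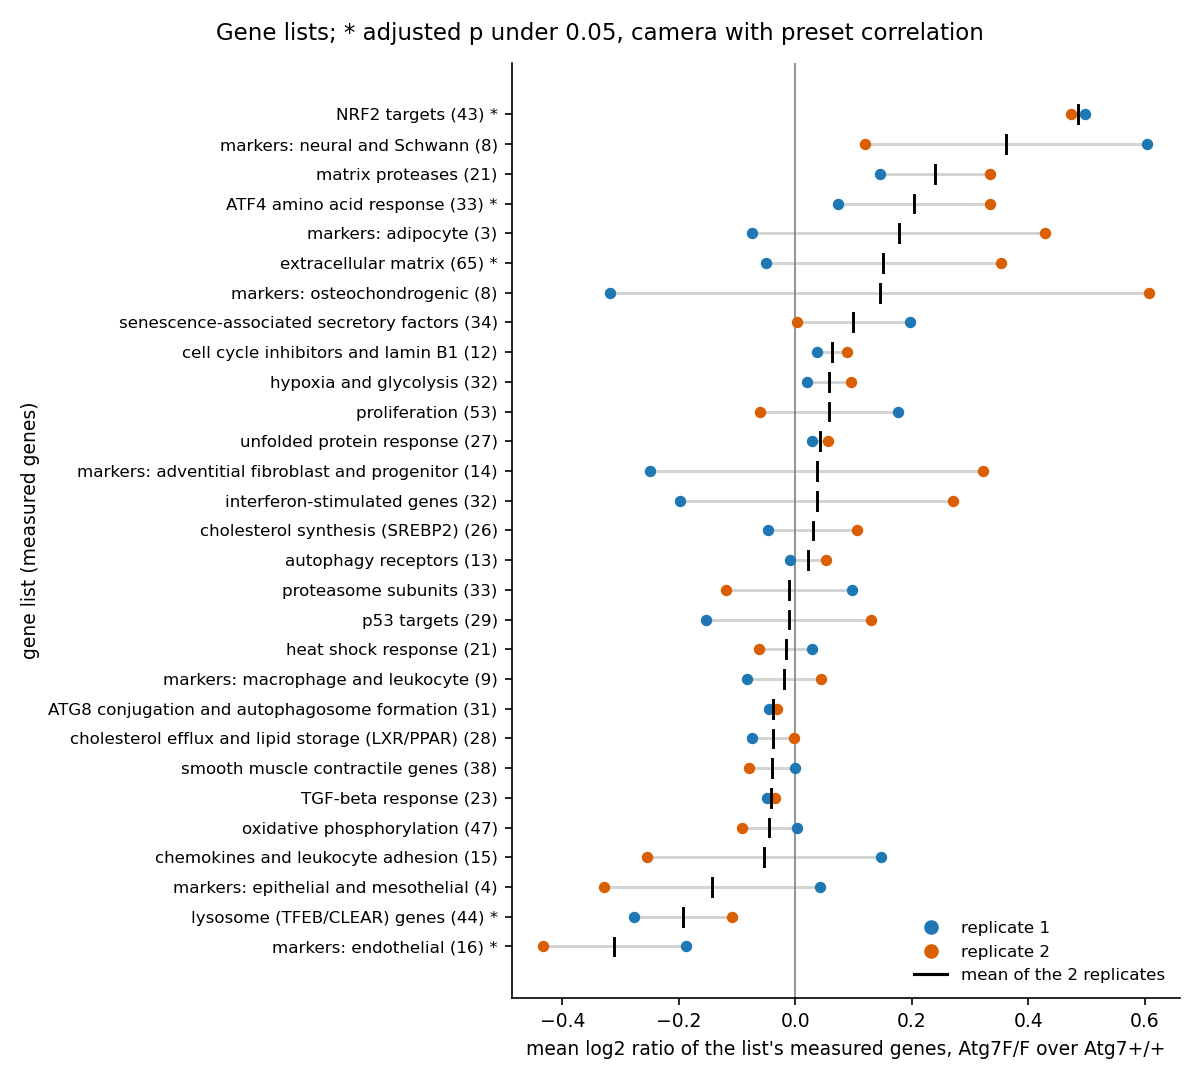
Mean log2 ratio (horizontal axis, Atg7F/F over Atg7+/+) of each gene list (vertical axis, number of measured genes in parentheses) in replicate 1 and replicate 2, with the mean of both as a black line and a star on the 5 lists called by camera with its preset correlation. NRF2 targets lie at 0.50 and 0.47, while extracellular matrix genes lie on both sides of 0, at -0.05 and 0.35.

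The dye-swapped arrays of a replicate gave similar ratios across genes, with a correlation of 0.69 in replicate 1 and of 0.81 in replicate 2, but the ratios of replicate 1 and replicate 2 correlated at -0.10. These are correlations across genes, which are not independent replicates. On both arrays of replicate 1, 88 genes were at least 2-fold apart, and on both arrays of replicate 2, 137. In opposite directions in the 2 replicates were 10 genes, where 0.466 would be reached if the replicates were independent. The histone deacetylase Hdac1 had 3.19 in replicate 1 and -3.91 in replicate 2, and the neuropeptide Cck had 1.64 and -2.61. In replicate 1, 10 genes at least 2-fold apart lay in a 4.06 Mb interval of chromosome 2, at 118574195 to 122635017 of mm9, 5 of them higher and 5 lower. These 10 made up 13.7% of the 73 genes tested there, against 0.629% of genes elsewhere. The interval was the run with the most such genes at gaps of at most 2 Mb. It ended at its outermost such genes, so a high share inside was fixed in advance. By the same rule replicate 2 gave 4 genes on chromosome 11, 10.5% of the 38 tested there against 1.05% elsewhere. The ratios of the 10 genes on chromosome 2 lay between -0.31 and 0.06 in replicate 2. The genes were Eif3j1 (1.93 in replicate 1), Jmjd7 (1.81), Rpap1 (1.66), 5430417L22Rik (1.56), Frmd5 (1.39), Exd1 (-1.07), Tmem87a (-1.11), Ppip5k1 (-1.12), Gchfr (-1.66) and Sqor (-1.69). The other probe of Eif3j1 had a mean of 0.00 over the replicates, against 0.81 for this one. A probe under Hisppd2a, an older name of Ppip5k1, lay in the same interval at 0.81 in replicate 1. The direction of Ppip5k1 there is therefore uncertain. Hdac1, Cck and the genes of this interval were chosen after their values were seen.

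**Figure D3:**
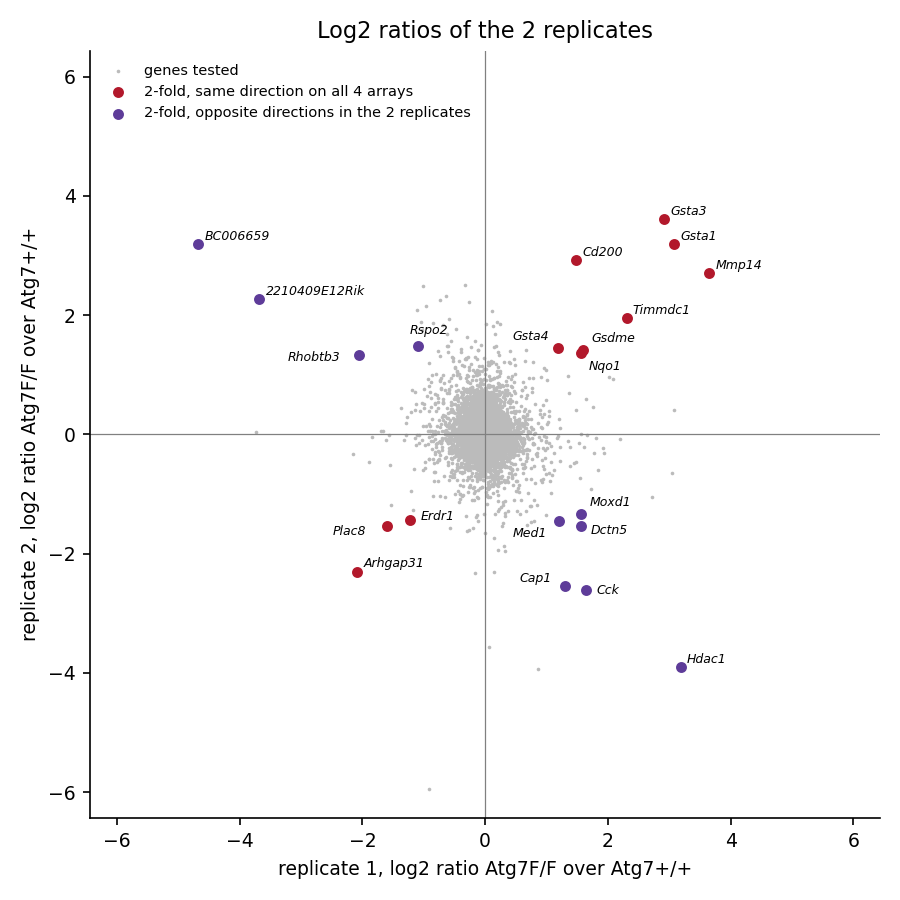
Log2 ratio of each of the 12367 genes tested (Atg7F/F over Atg7+/+) in replicate 1 (horizontal axis) and in replicate 2 (vertical axis). The 11 genes at least 2-fold apart in one direction on all 4 arrays are red and the 10 genes 2-fold apart in opposite directions are purple; the correlation across genes is -0.10.

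**Figure D4:**
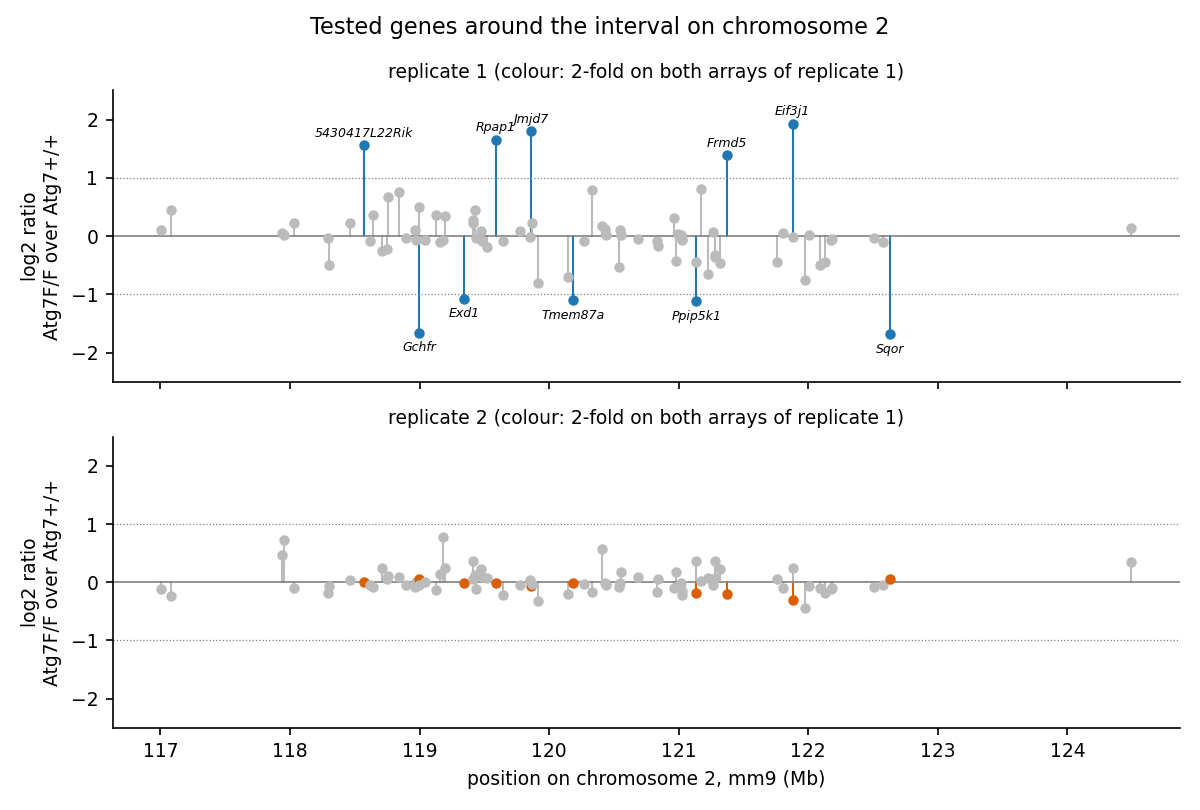
Log2 ratios (vertical axes, Atg7F/F over Atg7+/+) of the tested genes in and within 2 Mb of the chromosome 2 interval, by position in mm9 (horizontal axis, Mb), in replicate 1 (top) and replicate 2 (bottom). The 10 coloured genes lie between -1.69 and 1.93 in replicate 1 and between -0.31 and 0.06 in replicate 2.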

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

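No gene was called except with the pair of dye-swapped arrays as a random block, which called 7 higher and 2 lower, and without the replicate block, with unpaired extracts, which called 1 higher and 0 lower. Fitted to channel signals, the replicate block gave 0 genes and the same 5 lists, as the main test did. The Atg7 log2 ratio of -1.22 was -1.73 with an offset of 0, -1.33 without background subtraction and -2.35 with the software's processed signals or the deposited log2 table. The counts of 8 genes at least 2-fold higher and 3 lower on all arrays became 23 and 20 with the processed signals or the deposited table, 5 lower without background subtraction and 1 lower with median centring. With 1 replicate left out, only the 2 arrays of the other had to reach 2-fold, and the counts were 52 to 85 higher and 36 to 52 lower. Of 5 lists called, 0 were called with an estimated correlation and 0 with fry, and 9 were called with every probe tested. Leaving out replicate 2 turned the extracellular matrix list from 0.15 to -0.051, and leaving out replicate 1 to 0.353. The cause was not tested for these or the changes above, except that an offset pulls ratios towards 0. In 12 of 14 tested settings each of the 5 lists was called, with means of 0.44 to 0.63 for NRF2 targets, -0.23 to -0.12 for lysosome genes, -0.50 to -0.27 for endothelial markers, 0.17 to 0.28 for the ATF4 response and 0.13 to 0.23 for the matrix. All 12 kept the preset correlation of 0.01, so they do not show that the calls hold under another list test. Among them, the replicate block repeats the main test and the deposited table repeats the processed signals. The estimated correlations were above the preset for lysosome genes (0.28), endothelial markers (0.20), the ATF4 response (0.18) and the matrix (0.35). For NRF2 targets it was -0.019. Proliferation genes were called higher in 5 alternatives, contractile genes lower in 2, and chemokines and neural markers in 1 each. For the 132 named genes, the 4 settings that recompute the ratios (no offset, no background subtraction, processed signals and median centring) gave 528 values, of which 105 moved by at least the SD between replicates and 7 changed sign. Without replicate 1 or 2, 5 and 7 genes changed sign. Most of these genes were named for a small p over both replicates, so few sign changes were likely in advance. With the processed signals Slc7a11 went from 0.29 to 1.39, Cdkn1b from 0.40 to 0.93, Gsta4 from 1.32 to 2.32, Ints13 from -1.36 to -2.56 and Arhgap31 from -2.19 to -3.39. A trended prior moves neither ratios nor the list test, and leaving out a replicate gives values without a test. Only 43.3% to 45.5% of the spots per channel were well above background, which limits what these arrays show about weakly expressed genes.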

Other observations

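The tests of array noise, neighbours outside the chromosome 2 interval, exchanged genotypes, chance placement, second probes, sequence near Atg7 and transferase probes were chosen after the result was seen; those of inherited sequence in replicate 1 and in replicate 2 were written before. Outside the fixed lists, some genes with an unadjusted p below 0.01 and one direction on all 4 arrays lay within 2 Mb of each other. Timmdc1 (2.13) and Arhgap31 (-2.19) have probes that start at 38498991 and 38598803 of chromosome 16 in mm9 and moved in opposite directions in both replicates. On chromosome 6, Gpnmb (-0.88) lay near Gsdme (1.50), and Ints13 (-1.36) near Ppfibp1 (0.94, and 0.19 by its other probe).

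The Y-linked transcripts Ddx3y, Eif2s3y and Kdm5d were well above background on both arrays of replicate 1 in both genotypes and on 0 arrays of replicate 2, while 1 Xist probe showed the reverse. A second Ddx3y probe and all probes of the Y-linked Uty were not well above background on any array, nor were the other Xist probes. The 2 extracts hybridised together therefore matched in these sex-linked transcripts, while replicate 1 and replicate 2 differed in them. Whether this difference bears on the ratios that the replicates do not share was not tested.

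The log2 ratios of replicate 1 and replicate 2 did not correlate across genes. Array and dye noise is argued against by the dye-swapped arrays, whose lower correlation was 0.693, and an exchange of genotypes in 1 pair by Atg7, whose highest ratio was -0.962. In replicate 1, the 87 genes with a position that were 2-fold apart had 23 neighbouring pairs of opposite direction against a mean of 5.50 in random draws (a share of 1e-05, the smallest the draws can give) and 18 of the same direction against 5.81 (4.6e-04). The 10 genes of the chromosome 2 interval made 17 and 12 of these pairs, and the other 77 genes made 6 of opposite direction against 4.28 (a share of 0.265) and 6 of the same direction (0.310), while in replicate 2 there were 14 of opposite direction against 12.5 (0.377), which decides nothing. Inherited sequence that differs between the animals of replicate 1 may therefore account for the genes of that interval, 10 of the 88 genes 2-fold apart; for the other genes it stays open, and clonal growth and passage number, which the labels do not give per replicate, were not tested.

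The second pattern is that genes of small p lie close together. Chance placement is not excluded, since 6 neighbouring pairs of opposite direction among 59 genes were reached in a share of 0.0567 of draws, against a mean of 2.61. A cause in single probes cannot be told apart from a change of the transcript, since second probes had the sign of the first on all 4 arrays in 61.9% of 21 genes. Donor sequence around the engineered allele stays open, since, Atg7 itself set aside, none of these genes was among the 176 tested within 20 Mb of it, so the 0 of 12 neighbouring pairs there was fixed in advance. On chromosome 6 as a whole 7 of the genes other than Atg7 lay, against 2.85 in draws, a share of 0.0223.

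The third pattern is the rise of NRF2 targets. Probes shared between glutathione S-transferases are argued against as its whole cause by the other members. Their mean was 0.32, and 12 of 33 were higher and 0 lower on all 4 arrays. Without the transferases the list's adjusted p was 1.99e-08 with camera's preset correlation, which does not measure the spread between replicates. The other list tests were not run on this shorter list. Its cause stays open, as a response to loss of Atg7 was not tested apart from other differences between the cells. The full list was not called with an estimated correlation, a test with little power at so few replicates.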
